A study of Caenorhabditis elegans with 2 samples.

How the data were processed

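AMA-1, the large catalytic subunit of RNA polymerase II, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adult Caenorhabditis elegans of mixed sex. Per the labels, the worms were of strain YL503, which carries an inserted construct. In this construct the promoter of pie-1, a germline gene, drives AMA-1 fused to GFP and FLAG tags, and unc-119(+) serves as the marker. The labels name ama-1 as the antibody target, and whether the antibody bound the tag or AMA-1 itself is not given in the sources used here. Chromatin was fragmented by sonication, per the labels. The 2 samples are biological replicates of 1 group, so no comparison between conditions exists, and a listed control library was not used here.

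The authors deposited peak lists on the ce10 and ce11 assemblies. Per the file lists deposited beside the samples, relaxed lists, which hold peaks and background, were made for replicate 1, for replicate 2 and for the pooled reads, each against a control. A thresholded list, labelled optimal, was then made from these by the irreproducible discovery rate, a method that compares the ranks of peaks between replicates. A place in this list does not mean that a peak was found in both biological replicates. On ce11, 710 of its 732 peaks had a relaxed peak in each. The aligner and the peak caller are not given in the sources used here. In every deposited list each peak has a signal, which is the authors' own value for that peak, and a −log10 of a q-value. The signal was used only to describe, rank or filter peaks within a list. The −log10 q-value was the same for all peaks of each thresholded list and was not used to rank. The deposited files used here give no read counts, so the depth of each library is unknown, and no interval for a single peak's signal is given. Intervals on shares and odds ratios cover the sampling of peaks or genes only.

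Peaks were read with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and tests used scipy 1.17.1. Positions are 1-based and on ce11 unless ce10 is named, and none was converted between assemblies. Genes were taken from Ensembl release 115 for WBcel235, the assembly that ce11 names, with 19985 protein-coding genes, of which 19973 are nuclear. The NCBI annotation of the same assembly gave tRNA products and mitochondrial gene names. A gene was counted as carrying a peak where a summit of the ce11 thresholded list lay within 500 bp of its annotated start. Spliced leader (SL) RNA genes were those named sls. Operon-like genes were those whose start lies up to 500 bp after the end of another protein-coding gene on the same strand, since operons themselves are not annotated there. Chromosome centres were the middle of each autosome when its length is cut into 3 equal parts.

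Sets of genes were compared with two-sided Fisher exact tests, with conditional odds ratios and 95% intervals. The 22 gene lists were adjusted together by the Benjamini-Hochberg method, with all other protein-coding genes as background. Positions of summits, non-coding classes and the overlap of replicates were compared with 1000 circular shifts of the peaks within each chromosome. The smallest p these permutations can give is 0.001 one-sided and 0.002 two-sided. Shifts on ce10 wrapped at the ce11 chromosome lengths. Neighbouring genes can share 1 peak and are not independent, so the Fisher p-values are approximate. Replicates were compared over the 732 highest-signal peaks of each, the length of the thresholded list. For the rank correlation each thresholded peak took the highest signal among the overlapping relaxed peaks of a replicate. Mitochondrial peaks, which share an interval, were matched on summits within 150 bp.

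The tests, lists, windows and naming rule were fixed before the data were examined. The rule names the 25 highest-signal thresholded peaks by the nearest protein-coding gene start within 1000 bp, else by the gene that holds the summit, else by a non-coding gene within 1000 bp, else by position. It also names up to 4 members per list with the highest-signal summit within 500 bp of the start, and ama-1, pie-1 and unc-119 always. The members of the spermatogenesis list that the rule would name are not reported here. Because mitochondrial peaks filled 23 of those 25 places, nuclear peaks among the highest 30 were also named, and gene ends were examined beside gene starts. These additions, with the members named by their gene ends and the non-coding genes named singly, were chosen after the values were seen. Other settings fixed at the same time were a stricter list of the 366 highest-signal peaks, each replicate alone, windows of 250 and 1000 bp, overlap with the gene body, the nearest start only, autosomal genes only, other definitions of overlap, and ce10. Settings added later were a window at the gene end, and leaving out mitochondrial peaks or peaks beside small non-coding genes (tRNA, rRNA, snRNA, snoRNA, SL RNA and miRNA).

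The procedures were tested on simulated data with 706 nuclear peaks. With random peaks, the test of summits near gene starts was below 0.05 in 1 of 40 runs, the tRNA test over 612 genes in 1 of 40, the X chromosome test over 19973 genes in 3 of 40, and the gene list test over the same genes in 2 of 880 list tests. The overlap test was below 0.05 in 0 of 20 runs and the annotation classes in 0 of 120 class tests with random peaks. With 141 peaks placed at gene starts, 61 at tRNA genes, or 16 at ribosomal protein genes, the matching test was below 0.05 in 40 of 40 runs each. With 235 shared peaks the overlap test was below 0.05 in 20 of 20 runs, with a median overlap of 33.4%.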

Results

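AMA-1, the large subunit of RNA polymerase II, was mapped in 2 biological replicates of young adult worms that carry a tagged copy of it. The thresholded ce11 list held 732 peaks, of which 706 were nuclear and 26 mitochondrial. The relaxed lists held 30000 peaks for the pooled reads, 30000 for replicate 1 and 27106 for replicate 2. The 732 thresholded peaks were exactly the 732 pooled peaks of highest signal, from 27.5 to 2942, and 672 of them were 304 bp wide. By chromosome there were 133 peaks on I, 100 on II, 144 on III, 136 on IV, 97 on V and 96 on X. On ce10 the thresholded list held 712 peaks, 686 of them nuclear, with 95 on X.

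The highest signals lay on the mitochondrial genome, which took the first 23 places of the list. Whether they reflect binding of AMA-1 to this genome was not tested, since no library without the tag was analysed here. Cytochrome b (CYTB) held the highest summit, at position 4732, with a signal of 2942 in the pooled list, 1602 in replicate 1 and 1345 in replicate 2. ND5, a subunit of respiratory complex I, followed with 2022 at position 12459, with 1311 in replicate 1 and 763 in replicate 2. ND2 reached 684, ND4 675, COX3 651, ND1 568, ATP6 543, COX2 492, ND6 429 and COX1 377 in the pooled list. Of the 26 mitochondrial peaks, 25 shared a single interval of 13369 bp on a chromosome of 13794 bp, so they mark local maxima within 1 enriched stretch. The highest nuclear signal was 95.5 in replicate 1 and 50.3 in replicate 2.

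Most of the strongest nuclear peaks lay at the ends of protein-coding genes or beside small RNA genes. The highest, at chromosome I 7585181 to 7585343, had a signal of 115.3 (95.5 in replicate 1 and 21.8 in replicate 2). It lay in an exon of D2030.12 and 60 bp past the end of prg-1, which encodes a germline Piwi protein. A peak of 106 at chromosome III 13464448 to 13464657 lay 91 bp before the end of ant-1.1, a mitochondrial ADP/ATP carrier, and 259 bp from the start of kel-3. Another of 106, at chromosome III 3869543 to 3869694, lay where the ribosomal protein gene rpl-3 and the oppositely oriented tir-1 end. A peak of 104.1 at chromosome IV 8377659 to 8377875 lay 70 bp before the end of nap-1, a nucleosome assembly protein, and 145 bp from the start of D2096.7. The peak past the end of pgl-1, which encodes a P granule protein, lay at chromosome IV 6974312 to 6974387 with a signal of 88.3 (61.2 and 26.0 in replicates 1 and 2). Others lay at the ends of rsp-8 (80.5), rpl-12 (79.8), hmg-12 (78.9), top-2 (77.2), hsp-60 (73.2), eef-1G (71.2) and htp-1 (71.2). The peak at top-2, a DNA topoisomerase, had a signal of 68.4 in replicate 1 and 3.53 in replicate 2. The second highest nuclear peak, 108 at chromosome V 8500541 to 8500643, lay in an intron of pxn-1 and 12 bp from the start of the snoRNA gene ZK994.7. Peaks at cutl-18 (102), frm-7 (87.1) and haf-9 (70.1) likewise lay in introns that hold a snoRNA gene. A peak of 80.3 inside ints-8 lay 25 bp from rpr-1, the RNA component of RNase P. A peak of 79.1 at chromosome IV 7800438 to 7800550 lay 1307 bp past the nearest protein-coding gene end and 33050 bp from the nearest non-coding gene.

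How far the 2 immunoprecipitations agreed was asked first. Of the 732 highest-signal peaks of replicate 1, 271 (37.0%) had a summit inside one of the 732 highest of replicate 2. Shifted peaks shared 3.82% on average (permutation p = 0.001, one-sided, the smallest the shifts can give). Without mitochondrial peaks 245 of 706 (34.7%) were shared, against 0.255% in shifts. Nearly all thresholded peaks had a relaxed peak in each replicate, 729 in replicate 1 and 713 in replicate 2. Such matches were likely from the outset, since the peaks come from the pooled reads and the relaxed lists hold background. No shifts were run for these matches, so they do not measure agreement. Across the 710 peaks found in both, Spearman's rho of the signals was 0.12 (95% interval 0.05 to 0.20) and Pearson's r of log2 signal was 0.47. Both are across peaks, which are not independent replicates. The mitochondrial peaks carried much of this relation, since across the 686 nuclear peaks found in both, rho was 0.03 (−0.05 to 0.11) and r was 0.02. The thresholded list is selected on the signal of the pooled replicates, and such a selection lowers the correlation between them, so this value does not measure how well the replicates match. Of the 30000 relaxed pooled peaks, 9677 were found in both replicates, and across these rho was 0.32. These peaks also come from the pooled reads and are limited to those found in both, so this value has a similar limit.

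**Figure D1:**
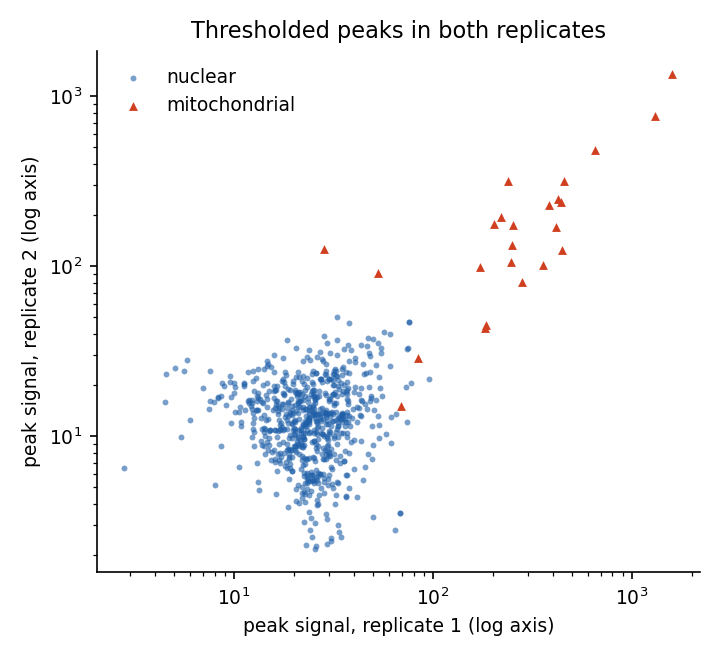
Signal of each thresholded peak in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, for the 710 peaks with a relaxed peak in both. Nuclear peaks (blue) form a cloud without a slope, and mitochondrial peaks (red triangles) reach 1602 and 1345.

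Where the polymerase subunit lay relative to genes was asked next. Summits lay near the starts of protein-coding genes more often than shifted peaks, and more often still near their ends. Of 732 summits, 259 (35.4%) were within 500 bp of a gene start, against 20.4% for shifted peaks, a ratio of 1.73 (permutation p = 0.001, one-sided, the smallest possible). Within 500 bp of a gene end there were 466 (63.7%), against 18.9%, a ratio of 3.37 (same smallest p). The gene end was examined after the data were seen. In nuclear bins of 100 bp, the most peaks around gene ends, 150, lay from 0 to 100 bp past the end. Around gene starts the fullest bin held 48, in the 100 bp before the start. Of the 706 nuclear peaks, 267 were near an end and no start, 64 near a start and no end, and 178 near both. These groups were not compared with shifts, so an excess at starts apart from ends is not shown.

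**Figure D2:**
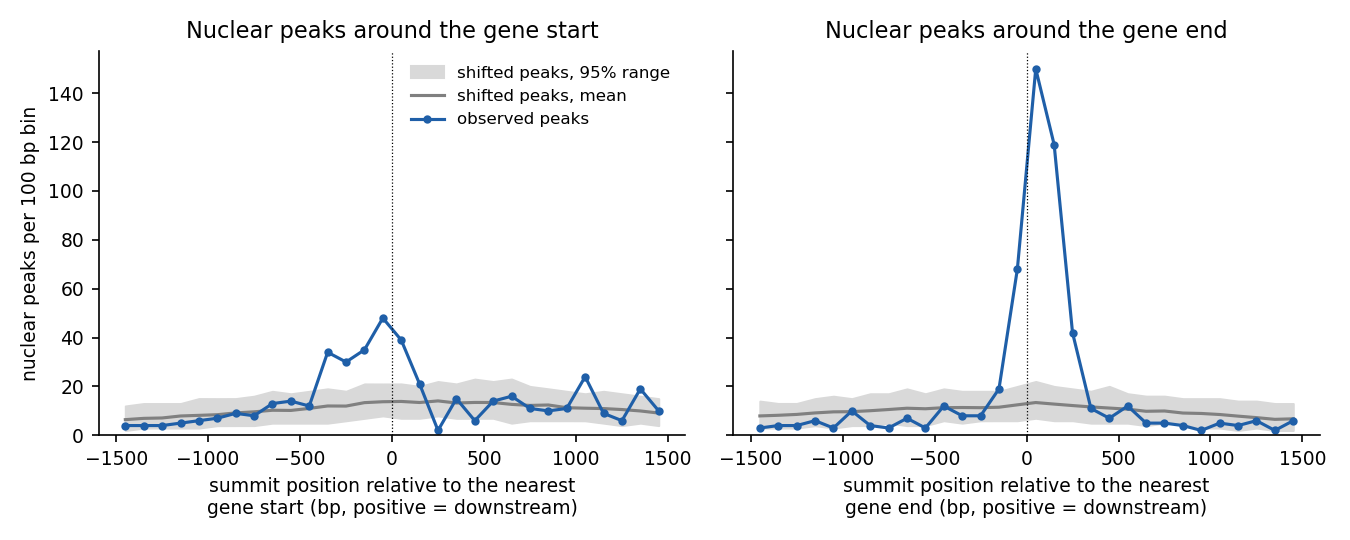
Nuclear thresholded peaks per 100 bp bin by the position of the summit relative to the nearest protein-coding gene start (left) and gene end (right), positive being downstream. The blue line is the observed count, and the grey line and band are the mean and the 95% range of 200 circular shifts; the count reaches 150 just past gene ends.

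The exclusive annotation classes gave the same ordering of excesses. Summits in 3' UTRs outside any start window numbered 95 (13%, against 2.63% in shifts), and those within 500 bp past a gene end 136 (18.6%, against 4.17%). The gene start window was assigned first and held the same 259, including those also near an end. Coding exons and 5' UTRs held 45 (6.15%, against 19.9%), introns 117 (16%, against 28.9%) and the remaining sequence 80 (10.9%, against 24.0%). Over the 6 classes, 3 were above and 3 below the shifts, each with an adjusted permutation p of 0.002, two-sided, the smallest possible.

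Cytosolic ribosomal protein genes, which are strongly expressed in most cells, carried peaks more often than other genes, and chemoreceptor genes less often. Among 22 gene lists, the ribosomal list had a peak by gene start at 15 of 82 against 1.28% of other genes (odds ratio 17.3, 95% interval 9.06 to 31.1, Fisher exact adjusted p = 5.72e-12). The odds ratio was 9.93 with replicate 2 alone, 7.67 in a window of 250 bp and 32.2 in a window of 1000 bp. The strongest were rpl-3, with a signal of 53.1 at chromosome III 3867446 to 3867749, 256 bp before its start, rps-16 (49.8), rpl-20 (43.6) and rpl-15 (42.1). In replicates 1 and 2 the rpl-3 peak had 43.3 and 16.3. Some ribosomal protein genes are shorter than the 500 bp window, so it reaches past their ends. The peaks counted at the starts of rpl-43 and rpl-41.2, for example, lay 157 and 98 bp past their ends and counted there too. Chemoreceptor genes, the large receptor families of sensory neurons, carried fewer peaks, 3 of 1309 (odds ratio 0.159, 0.0325 to 0.471, Fisher exact adjusted p = 3.26e-04). Their odds ratio was 0.0559 with replicate 2 alone and 0.103 with replicate 1 alone, and in a window of 250 bp it was 0.252 and not called. These 3 were srbc-58, sru-20 and str-141. No other list passed the adjusted test by gene start.

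Other lists by gene start held few genes with peaks. Translation factors had 2 of 45, tct-1 (67.5, with 61.6 in replicate 1 and 9.10 in replicate 2) and eif-3.C (38.2). mRNA splicing had 3 of 59, rnp-1 (44), snrp-200 (32.6) and snr-5 (29.8). Mitochondrial ribosomal proteins had 3 of 66, mrps-14 (53.4), mrpl-50 (31.8) and mrps-17 (29.1). Histones had 3 of 81, his-59 and his-60 at a shared peak (53.2) and his-61 (32.0), and since histone genes are near-identical copies these are uncertain. Oxidative phosphorylation had 2 of 43, cyc-2.1 (41.2) and atp-4 (30), and the transcription list had 2 of 77, mdt-22 (33.3) and cdk-7 (28.3). Spermatogenesis had 2 of 94. Germline and oogenesis had 1 of 51, cpg-2 (28.2), the proteasome 1 of 33, pbs-5 (29.8), cell cycle and DNA replication 1 of 63, cdc-48.1 (46.3), and the cytoskeleton of oocytes and embryos 1 of 52, arx-4 (29.5). C-type lectins and lysozymes had 1 of 250, clec-126 (31.7), and nuclear hormone receptors 1 of 269, nhr-49 (29.2). Meiosis (34 genes), intestine (39), muscle (40), cuticle collagen (175), neuron (138), chaperone (66) and F-box and BATH genes (395) had none, with an adjusted p of 0.0536 for the last.

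By gene end, the germline and oogenesis list was among several that joined the ribosomal protein list. The meiosis and spermatogenesis lists were not called. A peak lay within 500 bp of the end of 603 of 19985 genes, and 9 of the 22 lists were above and 4 below the other genes (Fisher exact tests, adjusted over the 22 lists). Cytosolic ribosomal proteins had 40 of 82 (odds ratio 32.7, 20.5 to 52.1, Fisher exact adjusted p = 1.20e-37), led by rpl-3, rpl-12, rpl-32 (76.9) and rla-0 (67.5). With replicate 2 alone the odds ratio was 16.5, from 24 of 82. Germline and oogenesis genes had 18 of 51 (odds ratio 18, 9.50 to 33.2, Fisher exact adjusted p = 4.06e-14), and 12 of 51 with replicate 2 alone (odds ratio 11.95). These included prg-1, pgl-1, the RNA helicase cgh-1 (64.2, with 51.6 and 16.3 in replicates 1 and 2) and the eggshell gene cpg-2 (57.6, with 53.6 and 9.73). The cytoskeleton of oocytes and embryos had 14 of 52 (Fisher exact adjusted p = 1.51e-09), with the tubulin gene tbb-2 (59.1) and the centrosomal gene spd-5 (57.8) highest. Translation factors had 11 of 45 (3.03e-07), among them eef-1G, eef-2 (63.7) and eef-1A.1 (53.8). Cell cycle and DNA replication had 12 of 63 (1.22e-06), with top-2, pcn-1 (55.7) and mcm-4 (51). The proteasome had 9 of 33 (1.24e-06), chaperones 12 of 66 (1.56e-06, with hsp-60 and hsp-1 at 59.3), mRNA splicing 11 of 59 (3.16e-06) and oxidative phosphorylation 5 of 43 (0.0184, with ant-1.1 and atp-1 at 50.5). In replicate 2 alone the proteasome had 6 of 33 and chaperones 7 of 66 (odds ratio 4.56, against 7.27). Oxidative phosphorylation was not called in replicate 1 alone (4 of 43, Fisher exact adjusted p = 0.0776).

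Chemoreceptor, nuclear hormone receptor, F-box and BATH, and neuron genes carried fewer peaks by gene end than other genes. Chemoreceptors had 3 of 1309 (Fisher exact adjusted p = 2.41e-13), nuclear hormone receptors 1 of 269 (0.0128), F-box and BATH genes 4 of 395 (0.0294) and neuron genes 0 of 138 (0.0398). The calls for neuron genes and nuclear hormone receptors were lost in replicate 2 alone (both 0.0875), and that for neuron genes also in replicate 1 alone (0.187). Chemoreceptors had 7 of 1309 in replicate 2 alone and 6 in replicate 1 alone (odds ratios 0.193 and 0.133, against 0.0692). Nuclear hormone receptors had 2 of 269 in each (0.282 and 0.228, against 0.118), and F-box and BATH genes 2 of 395 in each (0.190 and 0.154, against 0.324). Without mitochondrial peaks neuron genes stayed at 0 of 138, and the adjusted p was 0.0630. Without peaks beside small non-coding genes neuron genes stayed at 0 of 138 and F-box and BATH genes at 4 of 395 (odds ratio 0.382), and neither was called (both 0.0786) as fewer other genes had a peak. In that setting cuticle collagen (0 of 175) and C-type lectins and lysozymes (1 of 250) were called below the other genes (both 0.0435). Over all thresholded peaks, not called by gene end were meiosis (2 of 34, htp-1 and htp-2), spermatogenesis (1 of 94), intestine (1 of 39), muscle (2 of 40), cuticle collagen (2 of 175), C-type lectins and lysozymes (4 of 250), mitochondrial ribosomal proteins (1 of 66), histones (4 of 81) and the transcription list (2 of 77). Some of these peaks lay beside small RNA genes. The peak near the end of str-56 and nhr-102 lay 41 bp from the snoRNA gene T06C12.16, and the peak near the end of srxa-8 lay 59 bp from a tRNA-Val gene.

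**Figure D3:**
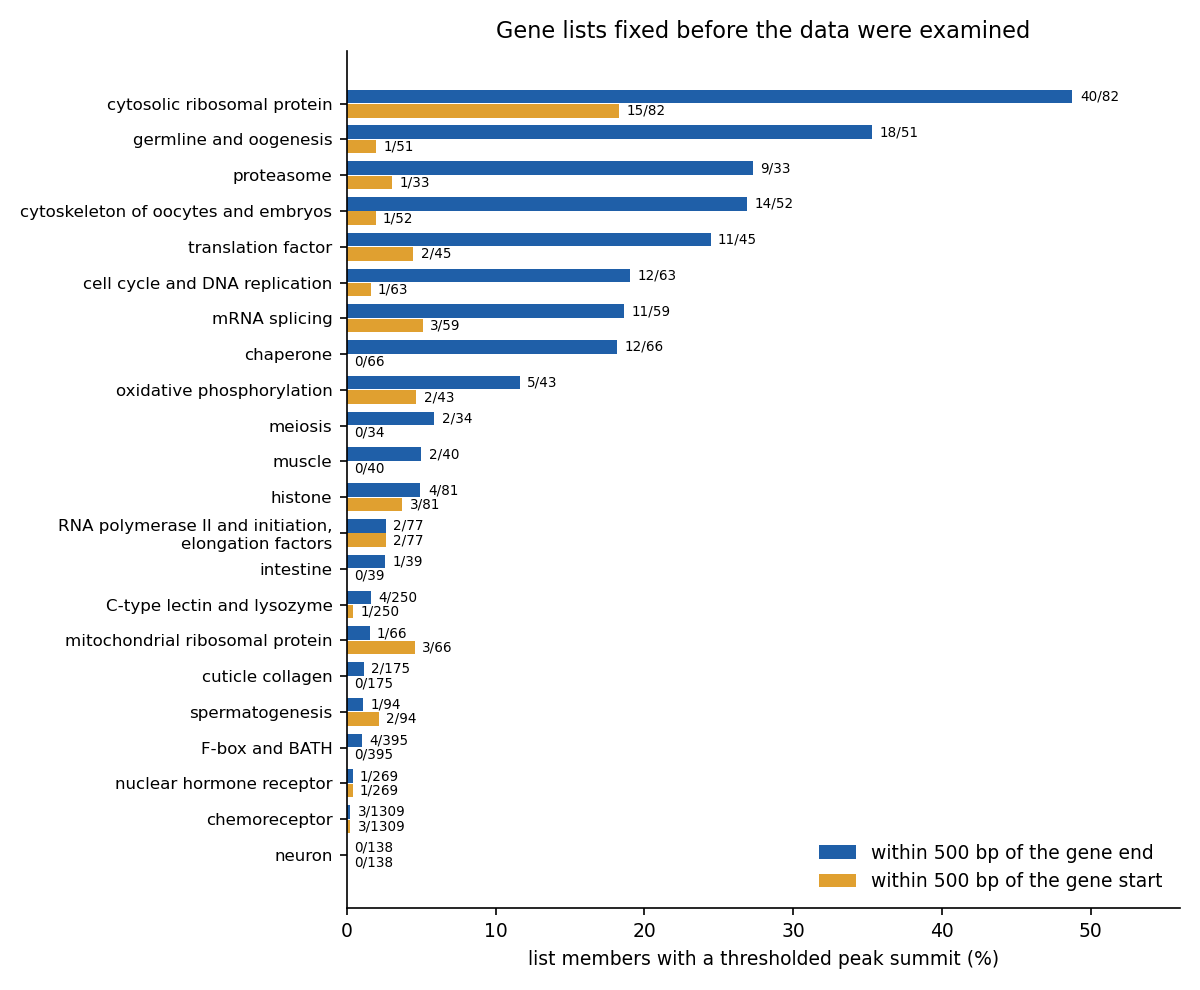
Percentage of the members of each of 22 gene lists with a thresholded summit within 500 bp of the gene end (blue) or the gene start (orange), with members carrying a peak over all members printed beside each bar. Cytosolic ribosomal protein genes lead both ways, 40 of 82 by end and 15 of 82 by start, and the germline and oogenesis list reaches 18 of 51 by end against 1 of 51 by start.

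The pair of genes rla-0 and tct-1 on chromosome I shows the placement. The peak at 10569067 to 10569370 had its summit 202 bp past the end of rla-0, a ribosomal stalk protein gene, and 107 bp after the start of tct-1, so it counted for both. The summit also lay inside the snoRNA gene F25H2.14, so this peak cannot be assigned to the end of rla-0 alone. A further peak at 10570103 to 10570178, with a signal of 67.0 (37.0 and 17.7 in replicates 1 and 2), had its summit 149 bp past the end of tct-1 and inside F25H2.12.

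**Figure D4:**
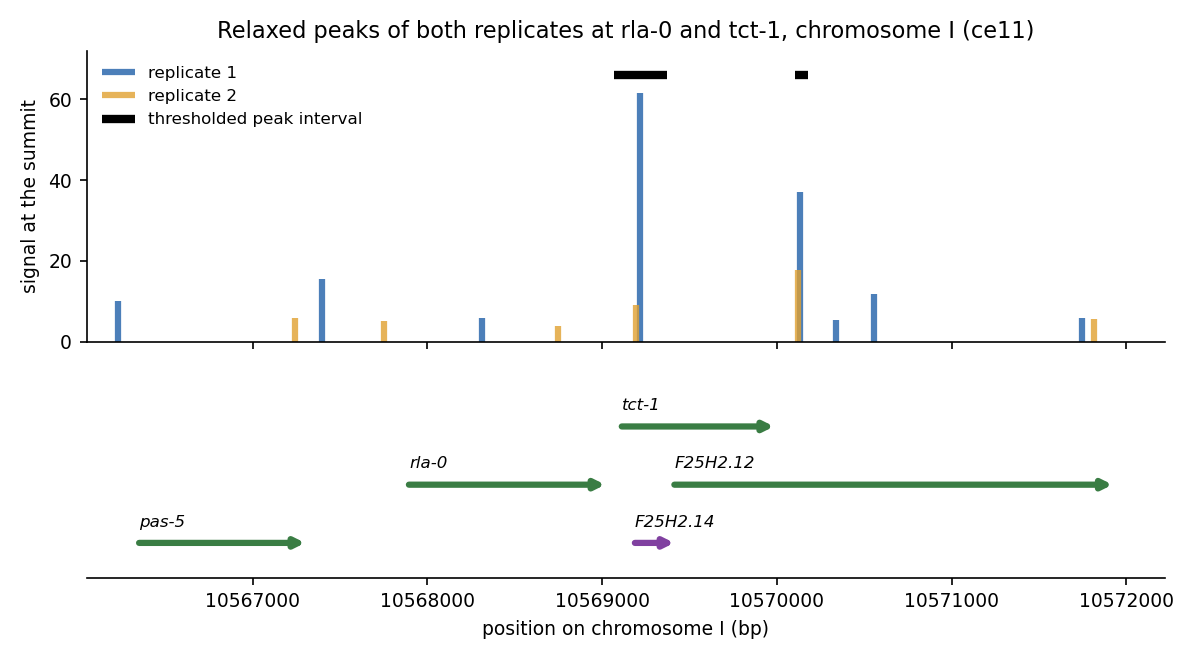
Signal of relaxed peaks (vertical bars at the summits, y axis) of replicate 1 (blue) and replicate 2 (orange) along chromosome I of ce11 (x axis, bp), with genes drawn as arrows below, protein-coding in green and the snoRNA gene in purple. Black bars mark the intervals of the 2 thresholded peaks, which lie past the ends of rla-0 and tct-1. The peak past rla-0 also has its summit inside the snoRNA gene.

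Genes on the X chromosome, which is known to be little transcribed in the germline, carried few peaks. By gene start 11 of 2731 X genes had a peak, against 246 of 17242 autosomal genes (0.403% against 1.43%, odds ratio 0.279, 95% interval 0.137 to 0.510, Fisher exact p = 9.06e-07). The odds ratio was 0.537 with replicate 2 alone and 0.145 with replicate 1 alone, 0.0773 in a window of 250 bp and 0.420 by overlap with the gene body. By gene end, 18 X genes had a peak against 573 autosomal genes (odds ratio 0.193). Without peaks beside small non-coding genes, 2 X genes had a peak at the start against 214 autosomal genes (odds ratio 0.0583). The X nevertheless held 96 of the 706 nuclear peaks. Of these, 84 (87.5%, exact 95% interval 79.2 to 93.4) lay within 500 bp of a tRNA gene, against 69 of 610 autosomal peaks (11.3%, 8.91 to 14.1).

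Genes in the central parts of autosomes and genes placed like downstream members of operons carried more peaks by start. In the centres 122 of 6570 genes had a peak, against 124 of 10672 in the arms (odds ratio 1.61, 1.24 to 2.09, Fisher exact p = 2.61e-04). Among the 366 highest-signal peaks the odds ratio was 1.33 (Fisher exact p = 0.166). Of 3621 operon-like genes 152 had a peak, against 117 of 16364 others (odds ratio 6.08, 4.74 to 7.83, Fisher exact p = 1.10e-45), with an odds ratio of 3.73 in replicate 2 alone. It was 10.2 in a window of 250 bp, 3.21 in a window of 1000 bp and 1.77 by overlap with the gene body. By definition these starts lie within 500 bp of the end of an upstream gene. Counted by their own ends, operon-like genes did not differ from others at the 0.05 level, with 127 of 3621 against 476 of 16364 (odds ratio 1.21, Fisher exact p = 0.0602).

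Small structural RNA genes were among the most frequent sites. Of 634 tRNA genes, 203 (32.0%) had a summit within 500 bp, against 4.01% for shifted peaks. The 22 mitochondrial tRNA genes raise both shares, and with nuclear genes and peaks only it was 181 of 612 (29.6%, against 0.639%). snoRNA genes had 65 of 346 (18.8%, against 0.745%), SL RNA genes, whose product is spliced onto mRNA 5' ends, 6 of 30 (20%, against 0.633%), and snRNA genes 6 of 99 (6.06%, against 0.706%). In replicate 1 alone tRNA genes had 143 of 634 and SL RNA genes 4 of 30, and in replicate 2 alone 209 and 7. The ratio to shifts for SL RNA genes was 19.4 in replicate 1 alone, against 31.6 over the thresholded list, 56.1 in a window of 250 bp and 18.3 in a window of 1000 bp. For tRNA genes it was 4.87 among the 366 highest-signal peaks, against 7.98, and for snRNA genes 16.7 and 4.42 in the windows of 250 and 1000 bp, against 8.58. For snoRNA genes it was 43.8 in the window of 250 bp, against 25.21. Among the 366 highest-signal peaks the ratio was higher for snRNA (14.8), snoRNA (40.5) and SL RNA genes (42.6). With nuclear genes and peaks only the tRNA ratio was 46.3. The tRNA ratios of 7.98 and 4.87 include mitochondrial genes, which hold the shifted share at 4.01% and 3.69%. They therefore do not show a weaker tRNA excess among the strongest peaks. Nuclear peaks near a tRNA gene numbered 153 in the thresholded list and 79 among the 366, for which no nuclear ratio was computed. Across 8 classes the adjusted permutation p was 0.004 for tRNA, snoRNA and SL RNA genes and 0.00639 for snRNA genes, two-sided. piRNA genes had fewer than shifted peaks, 25 of 15363 (0.163%, against 0.748%, adjusted p = 0.004). miRNA (3 of 261), lincRNA (2 of 194) and rRNA genes (2 of 22) did not pass the test. The 2 rRNA genes with a peak were mitochondrial, and of the 20 nuclear rRNA genes 0 had one. The snRNA count includes mir-1831, a microRNA by name that is annotated as snRNA, lies inside sup-39 and shares its peak. tRNA, snRNA and rRNA genes occur in near-identical copies, so which copy carries a peak is uncertain.

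Named examples among these genes had values in both replicates. The SL2-type genes sls-2.8 (80.1, with 54.6 and 30.8 in replicates 1 and 2), sls-2.4 (75.3, with 38.0 and 46.6), sls-2.1 (66.3, with 47.6 and 19.5) and sls-2.2 (54.4, with 33.2 and 19.6) led the SL RNA class. Those at sls-2.9 (30.8) and sls-2.18 (28.7) were weaker. Not all of these peaks belong to an SL RNA gene alone. The peak at sls-2.8 also lay 90 bp from the start of Y75B8A.23. The summit counted for sls-2.4 lay 249 bp after its start, past that gene and 17 bp before the end of R12E2.11, and the peak at sls-2.9 also lay 196 bp past the end of top-1. The snRNA gene R07E5.16 lay inside an intron of dhc-4 and had 84.5 (47.3 and 37.8). Of nuclear tRNA genes, a tRNA-Gly gene on X had the highest peak, 70.1 at 3035987 to 3036290 (55.7 and 17.3), followed by a tRNA-Asp gene on X near egl-17 (69.1) and a tRNA-Glu gene on X near F12D9.2 (68).

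**Figure D5:**
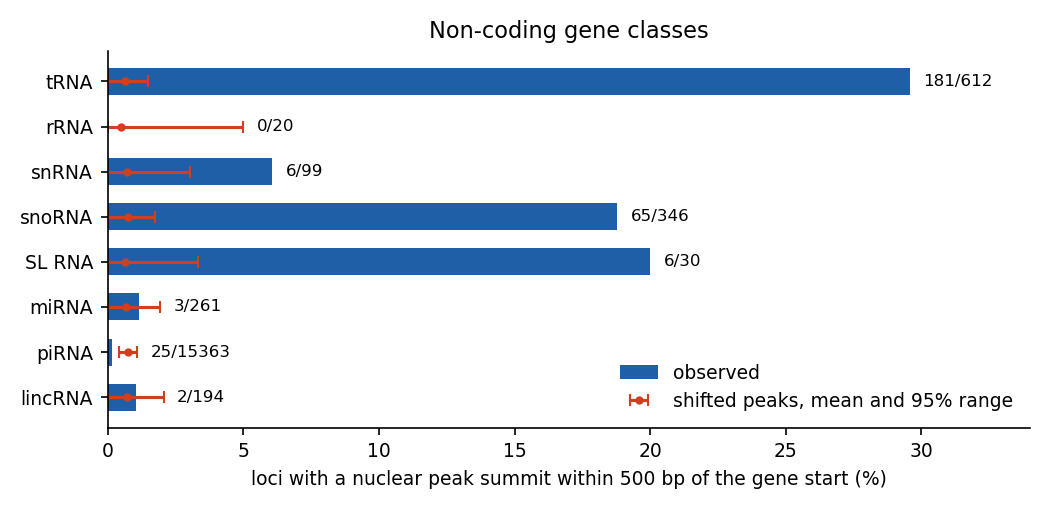
Percentage of nuclear loci of 8 non-coding gene classes with a nuclear peak summit within 500 bp of the gene start (blue bars, with loci carrying a peak over all loci). Red points and whiskers are the mean and 95% range of 1000 circular shifts, and tRNA (181 of 612), snoRNA (65 of 346), SL RNA (6 of 30) and snRNA genes (6 of 99) lie above them.

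The genes named in the construct, ama-1, pie-1 and unc-119, had no thresholded peak within or beside them, the lowest thresholded signal being 27.5. In the relaxed pooled list the highest peak at pie-1 had a signal of 26.5 (rank 807 of 30000) at chromosome III 12426567 to 12426870, just before the gene start. The highest at unc-119 had 26.2 (rank 824) and at ama-1 25 (rank 940, chromosome IV 4255358 to 4255661). In replicates 1 and 2 the highest signals were 16.5 and 10.4 at ama-1, 22.2 and 13 at pie-1, and 16.6 and 5.60 at unc-119. Reads of the endogenous genes and of the inserted copies cannot be separated in these lists.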

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

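The gene-end window, the lists without mitochondrial peaks and the lists without peaks beside small non-coding genes were chosen after seeing the data. No odds ratio for X genes, chromosome centres or operon-like genes changed direction in any setting. For the results below the cause was not tested unless stated. The odds ratio for chromosome centres fell to 1.33 (Fisher exact p = 0.166) among the 366 highest-signal peaks, a list with fewer peaks by construction, and that for operon-like genes to 1.21 (Fisher exact p = 0.0602) in the gene-end window. The replicate rank correlation of 0.12 became 0.319 over the 9677 relaxed pooled peaks found in both replicates and 0.0344 without mitochondrial peaks. Gene lists above the others by gene start numbered 1, and 3 in a 1000 bp window, 9 by overlap with the gene body and 9 in the gene-end window. Lists below numbered 1, and 2, 3 and 4 in those settings. In a 250 bp window 0 lists were below by Fisher exact tests, with 1 at an unadjusted p under 0.05, and the odds ratio for chemoreceptors was 0.252 (adjusted p = 0.0823). Using each replicate alone gave 1 to 2 lists above and 1 to 2 below by gene start, and 8 to 9 above and 2 to 3 below by gene end. On each replicate alone the odds ratios ran from 0.145 to 0.537 for X genes, 1.49 to 1.55 for chromosome centres and 3.73 to 6.78 for operon-like genes, and the ratio to shifts from 1.62 to 1.73 at gene starts and 2.87 to 3.42 at gene ends. No paired analysis was possible because there was 1 group. Read depth is not given in the lists, so its effect on the number of peaks was not measured.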

Other observations

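tRNA genes of most amino acids were represented among the peaks. The share of nuclear genes with a peak was highest for tRNA-Ala (16 of 34), tRNA-Lys (19 of 46) and tRNA-Thr (14 of 34), and among the lowest for tRNA-Gln (4 of 27), tRNA-His (3 of 20) and tRNA-Met (3 of 20). The selenocysteine tRNA gene had none. By chromosome, 102 of 276 X-linked tRNA genes had a peak (37.0%) against 79 of 336 on autosomes (23.5%), an odds ratio of 1.90 (95% interval 1.32 to 2.75, Fisher exact p = 3.59e-04). This comparison was made after the peaks on the X had been seen.

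The ama-1 gene held 15 summits of the relaxed pooled list within its 10100 bp. The 816 other nuclear protein-coding genes within 20% of that length held a median of 3, and 1 of them held as many. For unc-119 the count was 6, with a median of 1 among 1513 genes, of which 135 held as many. For pie-1 it was 3, with a median of 0 among 3848 genes, of which 340 held as many. Nuclear thresholded peaks narrower than 304 bp numbered 34, and 26 of these were among the 50 nuclear peaks of highest signal. Of the 706 nuclear peaks, 57 lay beside no protein-coding gene start, gene end or small non-coding gene.

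Of the tests that follow, the one on X chromosome peaks was chosen after its result was seen, as was the choice of all 3 patterns. The excess of peaks at the ends of protein-coding genes was set against 3 technical explanations. Of the 445 nuclear peaks near an end, 177 (39.8%, exact 95% interval 35.2 to 44.5) were also near the start of another gene. Most peaks near an end thus had no such start beside them. This share was not compared with shifts, so how much of the excess starts of neighbouring genes account for stays open. Small non-coding genes beside gene ends do not account for the excess as a whole. Among the 478 nuclear peaks away from such genes, 382 (79.9%) were near an end, against 17.2% in shifts. The median GC content around these summits was 36.8%, which is 3.98 percentage points (bootstrap 95% interval 2.99 to 4.48) above the same positions at genes without a peak, inside the bound of 5 points set for it. GC content was thus higher at these summits, and the bound was not tied to any effect on peak calling. No GC-matched comparison was run, so a contribution of GC content stays open. A candidate explanation that stays open is polymerase held past the end of transcribed genes, and general recovery of such regions in immunoprecipitation, whatever the antibody, stays open as well, since no library without the tag was analysed here.

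The excess of peaks at tRNA genes, which RNA polymerase III is known to transcribe, was set against 2 explanations. For reads shared between copies, 29 of the 143 nuclear tRNA genes whose exact sequence occurs once (20.3%) had a peak, against 0.648% in shifts (permutation p = 0.002, the smallest possible). This cannot exclude shared reads, since near-identical copies were not set apart. A summit at a neighbouring tRNA gene within 500 bp was counted as well. tRNA genes with sequences found more than once had 152 of 469 (32.4%). Nearby protein-coding starts and ends do not account for the excess at tRNA genes, since 85 of the 304 tRNA genes more than 1000 bp from any protein-coding start or end (28.0%) had a peak, against 0.655% (same smallest p). tRNA genes inside longer protein-coding genes were not set apart. Recovery of open or heavily transcribed chromatin regardless of the antibody was not tested and stays open, and no biological explanation was tested, since the design has 1 group.

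The X chromosome held 96 nuclear peaks although few of its protein-coding genes had one at the start. Peaks at tRNA genes are a candidate explanation. The odds of an X peak to lie near a tRNA gene were 54.3 times those of an autosomal peak (95% interval 27.8 to 115.04, Fisher exact p = 1.54e-52). Away from tRNA genes 12 X peaks were left. This ratio also reflects that the X holds 276 of the 612 nuclear tRNA genes. It reflects as well that few X peaks lay near gene ends (15 of 96, against 430 of 610 on autosomes). Counted per tRNA gene, the odds ratio for X against autosomes was 1.90. The hypothesis was found and tested on the same peaks, and whether the low number at X protein-coding genes reflects the germline promoter of the construct was not tested.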
